A study of Mus musculus with 7 samples.

How the data were processed

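The study is a droplet single-cell RNA sequencing series (10x Genomics Chromium, 3' chemistry) of mouse intestinal stroma. Per the labels, cells positive for a GFP reporter of Rspo3 were sorted from small intestine or colon, and the series design text adds that they lacked Epcam and CD45. The 7 samples form 4 groups: 2 of untreated small intestine, 2 of unirradiated control small intestine, 2 of small intestine from mice given 12 Gy, and 1 of untreated colon. No table of expression values for any of these samples was used here: the single processed file at hand was the gene annotation. Expression levels, cell numbers, depth per sample, cell types and the response to irradiation were therefore not analysed here. No expression test was run, and every number below describes gene models and not mice or cells.

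The deposited file is a gene transfer format annotation. Per the file headers it is GENCODE M23 (Ensembl 98) for GRCm38, and 5 records of source "hand" for an EGFP contig were added by the authors. Its values are 1-based start and end coordinates in bases, and the score field is empty in all 1780460 records. Per the submitters' processing notes, Cell Ranger 6.0.1, R 4.1.0 and Seurat 4.0.3 were used and the builds were GRCm38 and mm10. The labels give a Cell Ranger mkfastq version of 5.0.0 for the untreated small intestine and 6.0.1 for the other groups. How reads were assigned to genes, and which filters were set on cells, is not given in the sources used here.

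From the file, each gene's longest transcript (most exonic bases) was taken, and its last 500 exonic bases were called the 3' end, since reads of 3' libraries lie near the end of transcripts. The 3' end was called ambiguous where 1 base or more lay on an exon of another gene of the same strand (bedtools 2.31.1). Cell Ranger counts a read for a gene only where it fits 1 gene, so such bases can lower or remove a gene's count. The 3' UTR was taken as the exonic bases after the stop codon. A gene was left out of the 3' UTR lengths where its longest transcript had no coding sequence (2592 genes), had an end marked as not found (78 genes) or ended at the stop codon (771 genes). The longest transcript can be of a non-coding type or a target of nonsense-mediated decay (570 genes), in which case exons after an early stop codon count as 3' UTR. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3 were used.

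Before the data were examined, 17 gene lists were fixed for the sorted cells, the gates, niche signals and irradiation. They hold 240 different symbols, of which 6 stand in 2 lists. Each list was compared with all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the lists. The median 3' UTR of each list was placed among 10000 random lists of the same size drawn from protein-coding genes with a 3' UTR, with the same adjustment. Intervals are 95% Wilson intervals and cover counting error only. The rule for named genes was also fixed then: the R-spondins, Grem1 and any reporter, every list gene with an ambiguous 3' end, the genes with the longest and the shortest 3' UTR in each list, and every list gene with a near-identical copy. The test of all list genes together and the choice of the longest transcript of coding type were added after the results per list were seen.

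For sequence copies, GENCODE M21 transcript sequences of the same build were used, as no genome sequence was at hand. A transcript was used where its identifier, version and exonic length were equal in both releases, which held for 21357 protein-coding genes. Every 90-base word of the 3' end was searched in the sense sequences of all other genes, leaving out genes whose locus overlaps. The 141767 sequences hold 0 transcripts of genes on unplaced or unlocalized scaffolds, so copies there were not searched. Models that were extended between the releases can share more sequence than was found.

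The overlap, UTR and list functions were tested on simulated data. On a made annotation of 5000 genes they recovered the overlap of 5000 genes and the 3' UTR length of 5000 genes. Of 1000 random lists, 1.0% had a Fisher p below 0.05. Overlaps were planted at a higher rate than was found in the deposited annotation, so that percentage describes the made annotation only. Each made gene had a single transcript, so the choice among transcripts was not tested. Alternatives changed the window length, the kind, strand and size of overlap that counted, the transcript, the background and the treatment of missing 3' UTRs.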

Results

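The series was designed to profile stromal cells positive for a GFP reporter of Rspo3 in the normal and the irradiated mouse intestine. Rspo3 encodes the Wnt-enhancing ligand R-spondin 3. Small intestine contributed 2 untreated samples, 2 unirradiated control samples and 2 samples from mice that had received 12 Gy. Colon contributed 1 untreated sample. The labels do not say whether samples of a group came from separate animals. The groups imply a comparison of irradiated with unirradiated small intestine and a comparison of colon with small intestine. Expression values were not analysed here for either comparison, so no gene or cell type is reported as higher or lower in any group. The untreated small intestine was demultiplexed with version 5.0.0 of the software and the untreated colon with 6.0.1. The unirradiated control and the irradiated small intestine also carry version 6.0.1. The results below describe the gene models with which the libraries were to be counted.

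The deposited annotation held 32286 genes and 118154 transcripts on GRCm38. Protein-coding genes made up 21700 of them (67.2%) and long non-coding RNAs 9888 (30.6%). The remainder were immunoglobulin and T cell receptor segments and 1 reporter gene. The GENCODE release M21 for the same build listed 55536 genes, of which 32235 were in the deposited annotation. Of 13317 M21 pseudogenes outside the immunoglobulin and T cell receptor loci, 6 were present. Of the M21 micro RNAs 0 of 2207 were matched, of the small nucleolar RNAs 0 of 1507 and of the mitochondrial ribosomal RNAs 0 of 2, against 21702 of 22028 protein-coding genes.

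The reporter by which the cells were sorted was represented by 1 gene, egfp (EGFP, enhanced green fluorescent protein), on a contig of its own. It spanned bases 1 to 720 of that contig on the plus strand as 1 exon, and all 720 bases were coding sequence. Its 3' UTR was 0 bases long, and 500 of its last 500 exonic bases were coding. Among the 21700 mouse protein-coding genes, 771 (3.55%) had a complete longest transcript that ended at the stop codon. The egfp entry was also the 1 gene in the annotation without a transcript record and the 1 gene without a biotype.

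All 4 R-spondin genes, whose products amplify Wnt signalling through LGR receptors, had complete models with a 3' UTR. Rspo3 (ENSMUSG00000019880) lay on the minus strand of chromosome 10 from 29452416 to 29535867. Its longest transcript had 5 exons and 3085 exonic bases, of which 834 were coding and 1712 were 3' UTR. The 3' UTR measured 554 bases for Rspo1 (chromosome 4, 124986430 to 125009099), 1730 bases for Rspo2 (chromosome 15, 43020794 to 43170826) and 1537 bases for Rspo4 (chromosome 2, 151842927 to 151874668). Grem1, which encodes the BMP antagonist gremlin 1, lay on chromosome 2 from 113746164 to 113758646 and had a 3' UTR of 3436 bases. None of these 5 genes shared a base of its last 500 exonic bases with another gene of the same strand.

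**Figure D1:**
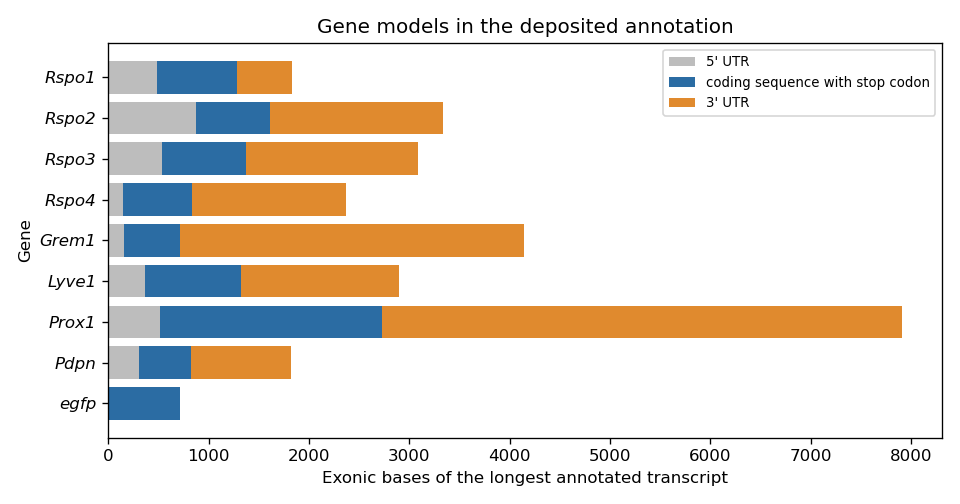
Exonic bases (x axis) of the longest annotated transcript of the 4 R-spondins, Grem1, the lymphatic endothelial genes Lyve1, Prox1 and Pdpn, and the reporter egfp (y axis), split into 5' UTR, coding sequence with stop codon and 3' UTR. The bar of egfp is 720 bases of coding sequence with no untranslated part, while the 3' UTR of Rspo3 is 1712 bases long.

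Of the 240 symbols in the fixed lists, 239 were found as protein-coding genes. No record was matched to Mx1, an interferon-induced antiviral gene, so that list had 17 of its 18 members. Every member was found for the lymphatic endothelial markers (15 of 15), the Grem1 fibroblast markers (17 of 17), the blood endothelial markers (16 of 16), the p53 and DNA damage genes (21 of 21) and the remaining lists. Ccl21a, a lymphatic endothelial chemokine gene, was the 1 list symbol with more than 1 gene identifier, so the 240 gene identifiers below stand for 239 symbols.

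Same-strand overlap at the 3' end was rare. It affected 213 of 21700 protein-coding genes (0.982%, 95% Wilson interval 0.859% to 1.12%), and in 119 of them (0.548% of all) a single other gene covered the whole window. The partner was protein-coding for 199 of the 213 genes and a long non-coding RNA alone for 14. In the 17 lists, 0 of 240 gene identifiers had such an overlap, against 2.38 at the rate of the other protein-coding genes. The two-sided Fisher's exact test gave p = 0.181 for all list genes together, and the Wilson interval reached 1.58%. As 0 is the lowest possible count, this pooled test could not detect a share below the background. No single list differed from the other genes by Fisher's exact test (adjusted p = 1.0 for each, 0 lists at an unadjusted p under 0.05). For 28 list genes, among them Lgr5, Dcn, Cd34 and Trp53, the longest transcript was not of coding type, so the window tested can differ from the end of their longest coding transcript. With the longest transcript of coding type the count was again 0 of 240. With 4 to 21 genes per list a share below the background could not be detected, and for the R-spondins the interval reached 49.0%.

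With either strand counted, 15 of the 240 list genes overlapped another gene, against 8.34% of all protein-coding genes. The genes named here were chosen after their values were seen. Among the BMP ligands, which oppose stem cell expansion in the crypt, the 3' end of Bmp4 shared 89 bases with Gm15217, that of Bmp5 500 bases with Gm26903 and that of Bmp6 224 bases with Txndc5. That list did not differ from the other genes (3 of 15 members, adjusted p = 1.0 by Fisher's exact test). These partners lay on the opposite strand, so the overlaps bear on counts only where reads of either strand are counted. The strand setting of the read counting is not given in the sources used here.

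A near-identical copy of the 3' end was found for 1 list gene, the lymphatic marker Ccl21a. Of 411 words of 90 bases in the 3' end of Ccl21a (chromosome 4, 42772860 to 42773993, minus strand), 262 (63.7%) also occurred in another gene, namely in Gm13304 and Gm21541. A smaller number, 18 words, occurred in Ccl21b and in Gm10591. The annotation held 6 gene identifiers named Ccl21a, Ccl21b or Ccl21c, of which 2 lay on chromosome 4 and 4 on scaffolds, whose sequences were not searched. Ccl21a was the 1 list gene of 236 searched with 50% or more of its words shared, compared with 956 of 21357 protein-coding genes (4.48%). Under the Cell Ranger rule given above, reads that fit more than 1 of these genes are not counted, so counts of Ccl21a can be too low. Oas1a, an interferon-induced RNA sensor, shared 42.3% of its words with Oas1g. The share was 8.52% for Ly6c1 with Ly6c2, 6.57% for Ifit3 with Ifit3b, 3.65% for Lyz1 with Lyz2, and 1.22% for Mki67 with a pseudogene.

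With the longest transcript, the R-spondin receptors and Wnt membrane regulators alone had 3' UTRs apart from random lists (adjusted p under 0.05). No list did with the longest transcript of coding type, a setting added after the results were seen. Of the 21700 protein-coding genes, 18259 (84.1%) had a 3' UTR on their longest transcript, with a median of 1070 bases (quartiles 391 and 2257). R-spondin receptors and Wnt membrane regulators had a median of 3518 bases over 8 genes, from 1339 for the ubiquitin ligase gene Rnf43 to 7934 for the Wnt co-receptor gene Lrp5. That median lay at percentile 99.9 of random lists of the same size (two-sided p = 0.0026 from random draws as a permutation test, adjusted p = 0.0442). The longest transcript of Lrp5 is annotated as a target of nonsense-mediated decay, with 8893 exonic bases, so that its 7934 bases include exons after an early stop codon. The longest transcript of coding type gave Lrp5 202 bases. With that choice for every gene, the list's median was 2277 bases over 9 genes, against 943 bases over 20795 protein-coding genes. That median was still the highest of all lists (percentile 97.2, p = 0.0555, adjusted p = 0.314 by the same permutation test). The list thus kept its direction but no longer passed the adjusted threshold.

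The BMP ligands and antagonists had a median of 2588 bases over 13 genes (percentile 99.3, adjusted p = 0.103 by the same permutation test), with 339 bases for Bmp4 as the shortest. The longest value, 5191 bases for Bmp1, again came from a transcript annotated for nonsense-mediated decay, and the coding transcript of Bmp1 had 557. The list was fixed by symbol, and whether each member, Bmp1 included, acts as a BMP ligand or antagonist was not tested. With coding transcripts the median was 1728 bases (percentile 94.8). Epithelial genes, which the Epcam gate excludes, had a median of 352 bases over 14 genes (percentile 0.895, adjusted p = 0.103 by the same permutation test), from 66 for Krt18 to 1631 for Cdh1. That percentile was 10.3 when genes without a 3' UTR counted as 0 bases. With coding transcripts it was 2.62 (p = 0.0525, adjusted p = 0.314 by the same permutation test).

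Cell type markers of the stroma lay nearer the middle of the random lists, apart from the telocyte and subepithelial fibroblast markers. The lymphatic endothelial markers had a median of 1019 bases (percentile 45.3), between 393 for Ccl21a and 5185 for Prox1, the transcription factor that specifies lymphatic identity. The Grem1 fibroblast markers had 921 bases over the 12 genes with a 3' UTR on their longest transcript (percentile 36.9). They ran from 43 for the complement gene C3 to 3101 for Pdgfra, which encodes a receptor for platelet-derived growth factor. The blood endothelial markers had 871 bases over 15 genes (percentile 30.4), between 56 for Ackr1 and 2616 for Flt1. That median was the value of Egfl7, whose longest transcript is annotated as a target of nonsense-mediated decay. With coding transcripts the median was 774.5 bases (percentile 30.5). Smooth muscle and pericyte markers had 1200 bases (percentile 60.8), between 80 for Actg2 and 6480 for Hhip. Telocyte and subepithelial fibroblast markers had 1700.0 bases (percentile 88.4), between 301 for Col6a4 and 6046 for Sox6. With coding transcripts that list lay at percentile 93.75 (adjusted p = 0.354 by the same permutation test). Glial and neuronal markers ran from 306 for Uchl1 to 5027 for Nos1 (median 1342, percentile 70.1), and mesothelial markers from 103 for Krt19 to 2393 for Upk3b (median 1268, percentile 61.6).

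Among the lists tied to signals and injury, the R-spondins had a median of 1625 bases (percentile 70.8) and the Wnt ligands and inhibitors 1899 (percentile 94.8), from 722 for Wnt6 to 4508 for Wnt5a. With coding transcripts the Wnt list lay at percentile 97.9 (adjusted p = 0.314 by the same permutation test). The p53 targets had a median of 1335 bases over 17 genes (percentile 72.0), from 150 for Gdf15 to 6692 for Zmat3. Interferon-stimulated genes had 736 over 13 genes (percentile 20.6), from 68 for Ifi27 to 3613 for Rsad2, whose coding transcript had 2660. Cell cycle genes had 603 (percentile 9.78), from 121 for Bub1 to 3352 for Cdk1. Stromal growth factors had 1666 (percentile 88.4, and 94.3 with coding transcripts), from 253 for Areg to 6308 for Igf1. Immune markers excluded by the CD45 gate had 952 over 10 genes (percentile 39.1), from 185 for Cpa3 to 2258 for Cd8a. These percentiles are across genes of an annotation, and genes are not independent replicates.

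**Figure D2:**
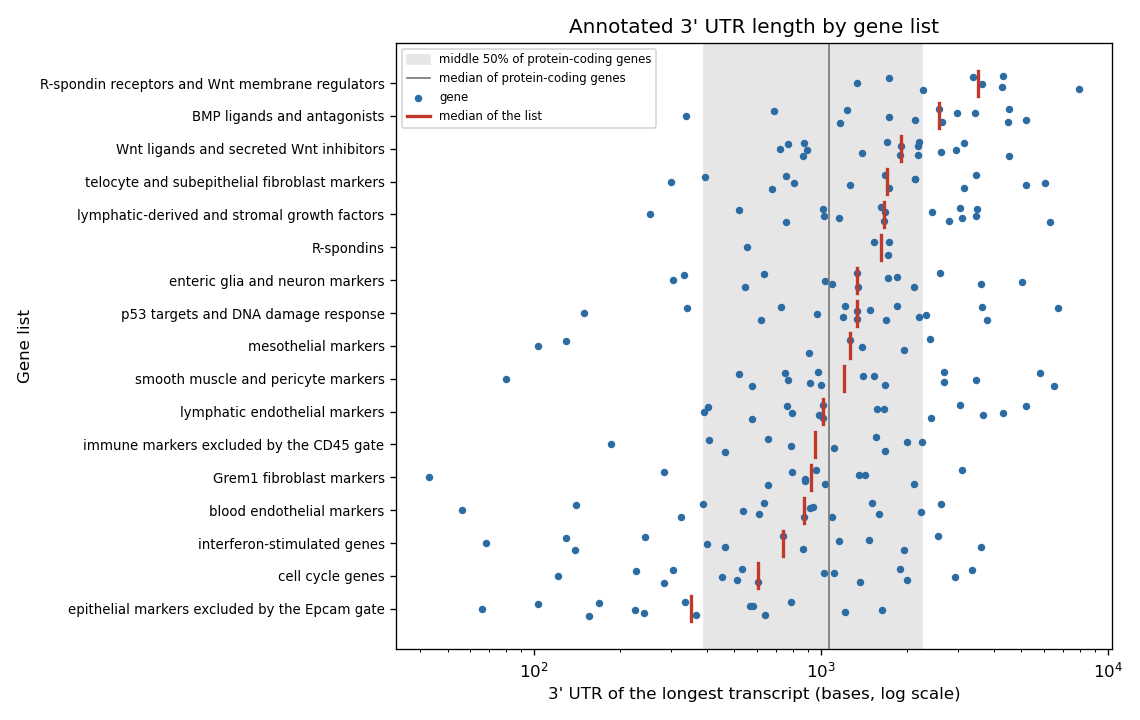
Length of the annotated 3' UTR in bases on a log scale (x axis) for the genes of each of the 17 lists (y axis). Points are genes, red bars are list medians, and the grey line and band are the median (1070 bases) and the quartiles (391 and 2257 bases) of all protein-coding genes; the receptor list lies highest at 3518 bases (2277 with coding transcripts) and the epithelial list lowest at 352.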

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

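The share of protein-coding genes with an ambiguous 3' end, 0.982%, moved to 1.21% with a window of 1000 bases, to 1.15% when the transcript ending farthest downstream set the 3' end, and to 8.34% when overlap on either strand counted. It stayed within its interval with a window of 300 bases (0.912%), with protein-coding partners alone (0.917%) and with an overlap of 50 bases or more (0.926%). Restricting partners to the biotypes of the standard 10x filter removed no partner, so that setting tests nothing. In each of these settings, and against the background with a 3' UTR, 0 lists differed from the other genes. With the transcript ending farthest downstream, 1 list gene became ambiguous: Ackr1, a venous endothelial marker, with 96 bases on Cadm3. With the longest transcript of coding type, a setting chosen after seeing the data, the share was 0.968% and the number of lists whose median 3' UTR lay outside the central 95% of random lists fell from 3 to 1. The receptor, BMP and epithelial lists lay inside (percentiles 97.2, 94.8 and 2.62), and the Wnt ligands and inhibitors, inside before, lay outside (percentile 97.9, adjusted p = 0.314 by the same permutation of lists). The receptor list then had an adjusted p of 0.314, with Lrp5 at 202 bases and Lgr5 added. The other 2 settings for missing or longer 3' UTRs left its adjusted p under 0.05 (0.0374 and 0.0408), but neither changes the value of Lrp5. The epithelial list moved from percentile 0.895 to 10.3 when genes without a 3' UTR counted as 0 bases. For the random lists this put 3441 genes at 0 bases into the pool, which lowers their medians. To the epithelial list it added Lgr5 alone. A value of 0 bases cannot raise the median of that list, so the rise in percentile came from the lower medians of the random lists. The Wnt list moved to percentile 98.4 with missing 3' UTRs as 0 bases, and the stromal growth factors to 97.7 with the longest 3' UTR of any transcript. Their adjusted values were 0.184 and 0.2. Matching symbols without regard to case again found 239 genes. No paired analysis was possible because no expression values of the samples were used. Depth per sample was not analysed here.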

Other observations

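For 26 of the 240 list genes the longest annotated transcript gave no 3' UTR, and for 25 of these another transcript of the same gene did. Among them were Ptprc, which encodes the CD45 antigen of the immune gate, with 1099 bases on another transcript, the fibroblast markers Cd81 (560 bases), Cd34 (1485 bases) and Dcn (488 bases), the stem cell receptor gene Lgr5 (1703 bases), and Trp53 (565 bases), which encodes p53. These genes were named after their values were seen.

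For the 213 genes with an ambiguous 3' end, the form of the readthrough test given here was chosen after the result was seen, and the 3' UTR test before. The form written before the result counted tagged partners only (30 genes) and was replaced because it left out genes that are themselves readthrough models and could hardly have reached a majority. If models that read through into a neighbouring gene were the main source, most of the 213 would be such a model or overlap one. The gene itself or a partner carried the readthrough tag in 44 genes (20.7%, 95% Wilson interval 15.8% to 26.6%). Within the deposited annotation, this argues against tagged readthrough models as the source for most of them, and leaves open readthrough models without the tag. The annotation lacks 326 of the 22028 M21 protein-coding genes. Whether those were readthrough models was not analysed, so the tagged share before filtering could differ. If long 3' UTRs reaching into the next gene were a cause, the median 3' UTR would be longer in these genes. It was 1128 bases in 169 of them and 1069 bases in 18090 other genes, a difference of 59.0 bases (two-sided permutation test with 10000 permutations, p = 0.6589), so this explanation stays open. No biological explanation was tested, since the design gives no group for gene models.

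The egfp entry ends at its stop codon, whereas 12820 protein-coding genes (59.1% of all) have a 3' UTR of 500 bases or more on their longest transcript. How many reporter reads lie outside the annotated 720 bases was not analysed here.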
